A study of Mus musculus with 6 samples.

How the data were processed

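Per the labels, total RNA was extracted from mouse liver with a column kit and made into libraries with a TruSeq kit from 200 ng per library; this kit does not keep the strand. There were 6 libraries, FFC_1 to FFC_3 and Chow_1 to Chow_3, grouped by the labelled diet. The submitters' processing notes name bcl2fastq, TopHat, Subread, featureCounts and the build mm10, without versions or roles. Per the file headers, the deposited table holds a count for each gene and library, an RPKM value for each gene and library, and a gene length in bases. The deposited counts were whole numbers with no normalization. The deposited RPKM values were counts divided by that length and by a read total per library that the authors do not state. That total, recovered from the values, exceeded the sum of the gene counts, which came to 92.4 ± 0.235% of it in FFC and 82.9 ± 2.10% in Chow (mean ± SD, n = 3 per group, exact 2-sided permutation p = 0.1). Counts were used for all tests.

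The table held 43346 genes, of which 25651 had a count in at least 1 library. Of the gene identifiers 98.0% were found in GENCODE M21, which uses the same build and gave gene types, exon overlaps and GC content. The 37 mitochondrial genes all stood at 0 counts, so they were not analysed. It was not tested whether their reads were left out or were counted at other genes. With a protocol that does not keep the strand, reads of overlapping genes on opposite strands cannot be separated. Counting overlaps on either strand, 1607 genes had over 50% of their exon bases under another gene (6.06% of counts). Among them were Trf and Gm20425, which overlap on the same strand. Depth ran from 61671717 to 83053480 counts. Counts of sequencing reads without molecular identifiers are not independent molecules, so counting intervals cover counting error only.

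Genes were kept with filterByExpr at a count minimum of 10, which left 17014. Libraries were scaled with TMM and compared with the robust quasi-likelihood test of edgeR 4.0.16 in R 4.3.3, 2-sided, with group as the only term and Benjamini-Hochberg adjustment at a threshold of 0.05. The common biological coefficient of variation was 0.156. Standard errors were derived from the log2 fold change and its F statistic. Gene lists were tested with camera in limma 3.58.1, 2-sided, with a preset correlation of 0.01, adjusted over 45 lists, and also with an estimated correlation and with fry. Shares of counts were compared with exact 2-sided permutation tests, where 3 against 3 libraries cannot give a p under 0.1. Further calculations used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, SciPy 1.17.1 and matplotlib 3.10.9.

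The gene lists, the rule for named genes, the tests and most alternatives were fixed before the data were examined. The lists covered lipid, sterol, bile acid, sugar and drug metabolism, matrix, liver and immune cell types, inflammation, stress, cell death, the cell cycle, sex-biased and clock genes, the respiratory chain, immediate early genes, and tissues that a sample might carry along. Genes could be named that had the largest changes without overlap of the groups at an average log2 CPM of at least 1, or the smallest p, or led their list, or were on a fixed set of liver disease genes, or were among the 5 most abundant. Of 205 such genes, 188 changed. The cytosolic ribosomal protein genes and the Y genes were chosen after values were seen. Results of some single genes are not reported here.

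The pipeline was tested on simulated data with the same depths and dispersions. Of 50 genes changed at each size, it recovered 42% at 1.5-fold, 78% at 2-fold, 96% at 4-fold and 98% at 8-fold. Of 16579 unchanged genes it called 14. It called the list with raised members, and 2 of 44 other lists. Genes were simulated independently of each other, and most were unchanged. These rates therefore do not cover correlation between genes, or scaling where most genes change.

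Alternatives were other scalings (DESeq2 size factors, upper quartile, library size alone), no filter, at least 50 counts in 3 libraries, DESeq2 1.42.0, limma-voom, a replicate block, thinning to 61671717 counts, removal of the gene length trend (lowess, span 0.4) without and with the block, the 20 most abundant genes left out, glmTreat against a fold of 1.2, and each library left out. The read total behind the RPKM values as library size, and leaving out overlapping genes and pseudogenes, were added after seeing the data. Reads were not available, so alignment and base quality were not examined.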

Results

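RNA from whole mouse liver was sequenced in 6 libraries. Per the labels, C57BL/6J mice aged 8 weeks at the start were kept for 30 weeks on chow or on the FFC diet, which holds much fat, fructose and cholesterol. The 3 FFC libraries are labelled as diet-induced nonalcoholic steatohepatitis (NASH), a fatty liver disease with inflammation and cell injury, and the 3 Chow libraries as pair-fed controls. Each library came from 200 ng of liver RNA. The labels give 1 mouse liver RNA per library and do not state more about separate animals, so the p-values measure the spread between these samples. Total counts were 78919368, 70183080 and 83053480 in FFC_1, FFC_2 and FFC_3, and 62898712, 61671717 and 72727045 in Chow_1, Chow_2 and Chow_3. FFC libraries held a count for 21974 ± 448 genes and Chow libraries for 20505 ± 250 (mean ± SD, n = 3 per group, exact 2-sided permutation p = 0.1, the smallest that 3 against 3 libraries can give).

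The comparison of FFC with Chow addressed how gene expression in the liver differs in a mouse model of diet-induced NASH. FFC livers held more RNA of genes for lipid droplet proteins, collagens, monocytes, lipid-associated macrophages and the cell cycle. They held less RNA of genes for cholesterol synthesis, secreted hepatocyte proteins, the mitochondrial respiratory chain and male-biased liver functions. Camera called these lists with a preset correlation, and none of the 45 lists with an estimated correlation, where these had adjusted p = 0.265 to 0.432. Among genes with a large change, Gpnmb, a glycoprotein of lipid-laden macrophages (ENSMUSG00000029816, chromosome 6, 49036518 to 49058182 on build mm10), stood at 67.2 ± 7.71 CPM in FFC and 0.700 ± 0.290 CPM in Chow (log2 6.56 ± 0.23, adjusted p = 8.75e-07). Hsd3b5, a steroid-metabolising enzyme of male mouse liver (ENSMUSG00000038092, chromosome 3, 98618636 to 98630309), stood at 0.624 ± 0.257 CPM in FFC and 355 ± 69.0 CPM in Chow (log2 -9.16 ± 0.36, adjusted p = 1.97e-06). In the edgeR quasi-likelihood test with Benjamini-Hochberg adjustment, 10794 of 17014 tested genes changed (63.4%), 5469 of them higher and 5325 lower in FFC. At least 2-fold changes numbered 4752, with 2626 higher and 2126 lower. The 3 FFC values lay all above or all below the 3 Chow values for 69.8% of tested genes, where chance gives 10%. The named genes given here as changed are all among them, as are 10648 of all 10794 changed genes. The split depended on the scaling: with library size alone 8891 genes were higher and 2755 lower (median of all genes shifted by 0.47 on the log2 scale), and with the read total behind the deposited RPKM values 10033 were higher and 2098 lower (shifted by 0.63). With the latter the medians of the hepatocyte secretory and the oxidative phosphorylation lists were -0.21 and -0.24, from -0.83 and -0.86. Of the 6 libraries, FFC_1 stood farthest out on the first principal component (80.8% of the variance), at -89.2 against -63.8 and -66.8 for FFC_2 and FFC_3 and 76.5, 75.2 and 68.0 for the Chow libraries.

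Gene levels are given as CPM, the usual scaling of counts to library size, with TMM factors (mean ± SD, n = 3 per group), and log2 fold changes as FFC over Chow ± the standard error of the edgeR fit. Of 45 gene lists, camera called 23, 17 higher and 6 lower, with a preset correlation between genes. With an estimated correlation it called 0, at adjusted p of 0.265 or more, and 5 lists had an unadjusted p under 0.05. In fry, which tests whether the genes of a list move on balance one way and does not compare them with other genes, 35 of the 45 lists passed. List counts adjusted over the list alone are given where they differ from those adjusted over all genes tested, and were the same for the other lists. Genes named without a value to complete a small count were chosen after their values were seen.

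**Figure D1:**
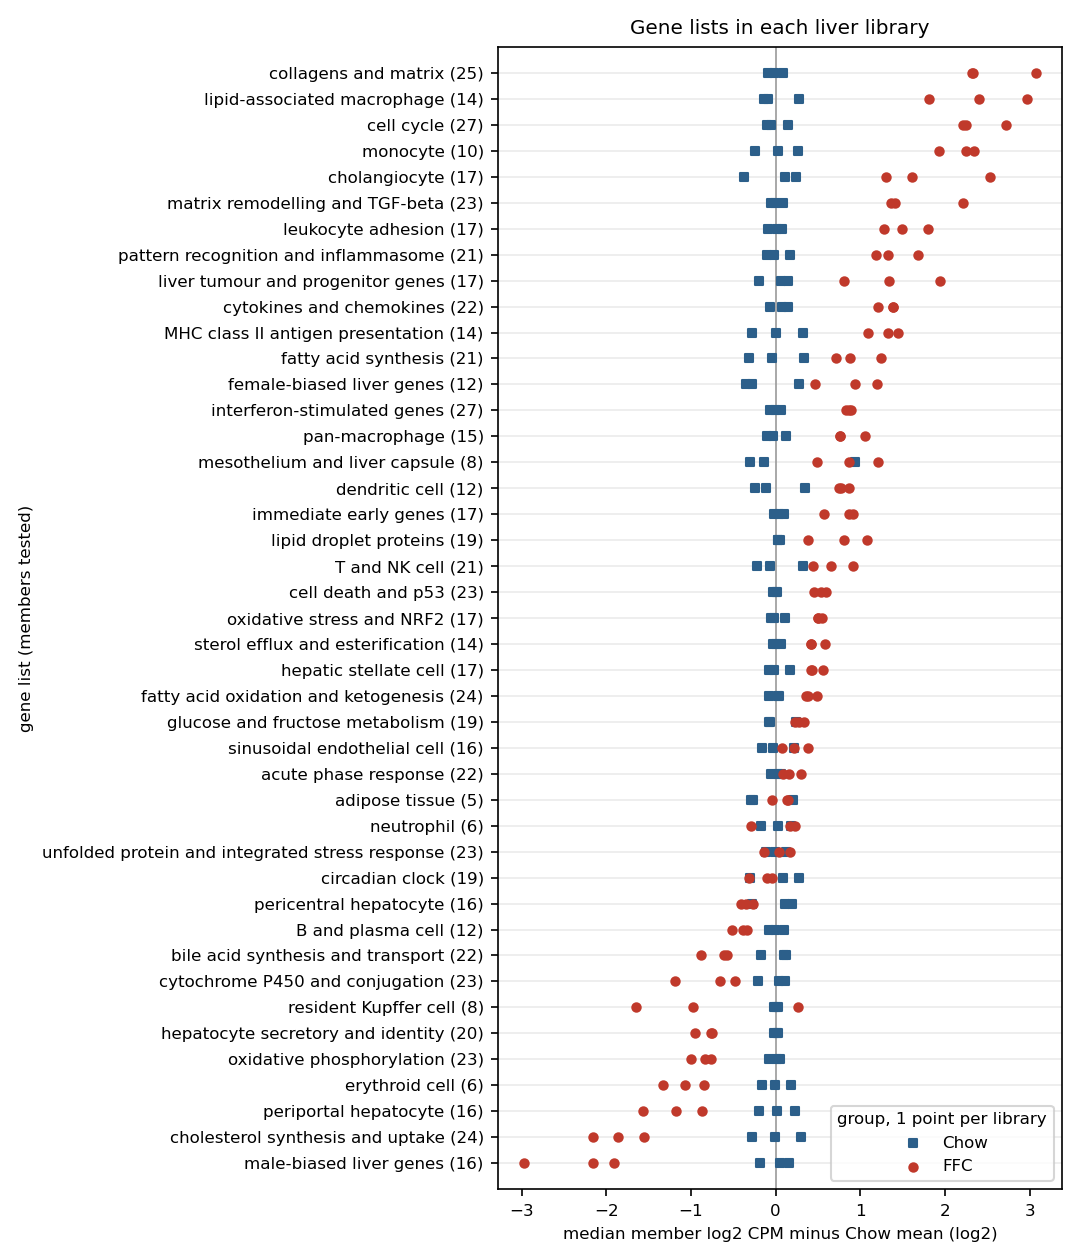
Median over each gene list's members of the log2 CPM in a library minus the mean of the Chow libraries, for the lists with at least 5 tested members (number in brackets), with 1 point per library. The FFC libraries lie between 2.33 and 3.08 for collagens and matrix, and between -2.97 and -1.91 for male-biased genes.

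Genes of lipid droplets, the fat stores of hepatocytes, rose. Plin4, a droplet coat protein (ENSMUSG00000002831, chromosome 17, 56100591 to 56109803), stood at 66.2 ± 8.43 CPM in FFC and 1.03 ± 0.107 CPM in Chow (log2 6.00 ± 0.14, adjusted p = 3.54e-08). Cidec, which fuses droplets into larger ones, stood at 106 ± 6.83 CPM in FFC and 1.76 ± 0.612 CPM in Chow (log2 5.90 ± 0.22, adjusted p = 1.01e-06). Cd36, a fatty acid transporter, stood at 338 ± 25.8 CPM in FFC and 58.5 ± 13.0 CPM in Chow (log2 2.53 ± 0.17, adjusted p = 2.74e-06), and the droplet coat gene Plin2 (log2 1.67 ± 0.14, adjusted p = 6.14e-06) rose as well. In the lipid droplet list 12 of 19 tested members rose and 2 fell (median log2 0.77, camera adjusted p = 2.40e-06, and adjusted p = 0.265 with an estimated correlation). The members that fell were Abhd5, a cofactor of triglyceride breakdown, and Fabp1, the fatty acid binding protein of hepatocytes. Its median in FFC_1, FFC_2 and FFC_3 was 1.07, 0.80 and 0.38 relative to the Chow mean.

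Enzymes that make fatty acids rose in part. Scd1, which desaturates fatty acids, stood at 37239 ± 9487 CPM in FFC and 6181 ± 2903 CPM in Chow (log2 2.59 ± 0.38, adjusted p = 0.000549). The desaturation and elongation enzyme genes Fads2 (1.05 ± 0.14) and Elovl5 (2.01 ± 0.25) rose too. Fasn, the fatty acid synthase, stood at 1683 ± 762 CPM in FFC and 268 ± 167 CPM in Chow (log2 2.65 ± 0.57, adjusted p = 0.0104, 3.29 without Chow_1). In the fatty acid synthesis list 12 of 21 tested members rose and 4 fell, or 13 and 4 adjusted over the list alone (median log2 1.05, camera adjusted p = 0.0692, called in 8 of 20 alternatives, among them without FFC_2, Chow_1 or Chow_3 at medians of 0.97, 1.08 and 0.86), so the list was not called. It held 5.26 ± 1.13% of all counts in FFC and 0.876 ± 0.255% in Chow (exact permutation p = 0.1), most of it Scd1. With the 20 most abundant genes, Scd1 among them, and the mitochondrial genes left out, the log2 ratio of its FFC to its Chow share was 1.25, from 2.59. Srebf1, a transcription factor of lipid synthesis, did not pass (log2 1.05 ± 0.38, adjusted p = 0.0513, passing in 7 of 21 alternatives, among them without Chow_1 at log2 1.49). In the fatty acid oxidation and ketogenesis list 14 of 24 tested members rose and 3 fell (median log2 0.41, camera adjusted p = 0.0206, and adjusted p = 0.427 with an estimated correlation). Pdk4, which restrains glucose oxidation, rose (log2 2.90 ± 0.32, adjusted p = 0.000441), as did Ehhadh (1.18 ± 0.12) of peroxisomal oxidation and Cpt1a (0.86 ± 0.10), which brings fatty acids into mitochondria. Fgf21, a hormone of fasting and nutrient stress, stood at 21.2 ± 12.9 CPM in FFC and 1.04 ± 0.323 CPM in Chow (log2 4.33 ± 0.58, adjusted p = 0.00153, 3.72 without FFC_2).

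Genes of cholesterol synthesis fell. Idi1, an isomerase of the pathway (ENSMUSG00000058258, chromosome 13, 8885501 to 8892451), stood at 17.8 ± 3.46 CPM in FFC and 637 ± 113 CPM in Chow (log2 -5.16 ± 0.20, adjusted p = 6.58e-07). Sqle, which oxidises squalene, stood at 5.26 ± 2.29 CPM in FFC and 98.5 ± 30.2 CPM in Chow (log2 -4.22 ± 0.43, adjusted p = 0.000558). In the cholesterol synthesis and uptake list 1 of 24 tested members rose and 21 fell (median log2 -1.86, camera adjusted p = 1.64e-14, and adjusted p = 0.427 with an estimated correlation), and its median was -1.40 with library size alone and -1.24 with the read total behind the RPKM values. In the sterol efflux and esterification list 7 of 14 tested members rose and 3 fell (median log2 0.51, camera adjusted p = 0.129, called in 3 of 20 alternatives, among them without FFC_1 at a median of 0.52). The sterol exporter genes Abcg1 (1.89 ± 0.097) and Abcg5 (1.06 ± 0.25) rose, as did Soat1 (1.85 ± 0.16), which esterifies cholesterol, while Nr1h3 (-1.15 ± 0.082), the sterol-sensing nuclear receptor, fell.

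Bile acid genes went both ways. In the bile acid synthesis and transport list 6 of 22 tested members rose and 14 fell (median log2 -0.68, camera adjusted p = 0.239). Cyp7b1, of the alternative pathway of bile acid synthesis, fell (log2 -3.64 ± 0.46, adjusted p = 0.00113), while Abcb4, which exports phospholipid into bile, rose (log2 1.51 ± 0.12, adjusted p = 5.32e-06). Cyp7a1, the rate-limiting enzyme of bile acid synthesis, stood at 20.6 ± 6.94 CPM in FFC and 193 ± 196 CPM in Chow (log2 -3.23 ± 0.90, adjusted p = 0.0306, -1.96 without Chow_1). It did not pass without FFC_1, FFC_2 or FFC_3 (adjusted p = 0.116, 0.0852 and 0.101), and its Chow values were 419.6, 84.3 and 75.1 CPM. In the glucose and fructose metabolism list 7 of 19 tested members rose and 4 fell (median log2 0.25, camera adjusted p = 0.247). Pck1, the gluconeogenic phosphoenolpyruvate carboxykinase, fell (log2 -1.21 ± 0.20, adjusted p = 0.000697), and Pcx (1.29 ± 0.14), the pyruvate carboxylase, rose. G6pc, the glucose-6-phosphatase, did not pass (log2 -0.71 ± 0.29, adjusted p = 0.0745, passing in 1 of 21 alternatives, namely without Chow_2 at log2 -0.92). In the cytochrome P450 and conjugation list 4 of 23 tested members rose and 13 fell (median log2 -0.65, camera adjusted p = 0.0894, called in 6 of 20 alternatives, among them without FFC_3 or Chow_3 at medians of -0.73 and -0.63). Cyp1a2, a drug-metabolising enzyme, fell (log2 -2.57 ± 0.26, adjusted p = 9.37e-05).

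Genes of the fibrous matrix rose. Col1a1, the main fibrillar collagen of scars (ENSMUSG00000001506, chromosome 11, 94936224 to 94953042), stood at 103 ± 54.1 CPM in FFC and 1.84 ± 0.177 CPM in Chow (log2 5.81 ± 0.50, adjusted p = 0.000283), with 165, 80.1 and 64.4 CPM in FFC_1, FFC_2 and FFC_3. Col3a1, another fibrillar collagen, stood at 233 ± 98.2 CPM in FFC and 18.2 ± 1.93 CPM in Chow (log2 3.68 ± 0.32, adjusted p = 0.000128). In the collagens and matrix list 25 of 25 tested members rose and 0 fell (median log2 2.60, camera adjusted p = 1.02e-13, and adjusted p = 0.427 with an estimated correlation). Its median was 3.08, 2.33 and 2.33 in FFC_1, FFC_2 and FFC_3, and 2.14 with the trend on gene length removed. In the matrix remodelling and TGF-beta list 21 of 23 tested members rose and 0 fell (median log2 1.78, camera adjusted p = 8.78e-07, and adjusted p = 0.427 with an estimated correlation). Among them were the collagenase gene Mmp13 (log2 5.37 ± 0.42, adjusted p = 1.05e-05, 6.01 without Chow_3), Timp1 (4.77 ± 0.45, 5.47 without Chow_2), an inhibitor of matrix proteases, and Tgfb1 (0.85 ± 0.11), a profibrotic cytokine. In the hepatic stellate cell list, markers of the liver's pericytes, 9 of 17 tested members rose and 0 fell (median log2 0.44, camera adjusted p = 0.0110, and adjusted p = 0.427 with an estimated correlation). The growth factor receptor gene Pdgfrb (log2 2.32 ± 0.17, adjusted p = 6.08e-06) rose. Acta2, a marker of activated stellate cells, did not pass (log2 0.73 ± 0.34, adjusted p = 0.0957, passing in 8 of 21 alternatives, among them without Chow_3 at log2 1.21).

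Macrophage and monocyte genes rose, while 6 of 8 tested markers of resident Kupffer cells did not pass the test. In the lipid-associated macrophage list 13 of 14 tested members rose and 1 fell (median log2 2.51, camera adjusted p = 1.02e-13, and adjusted p = 0.427 with an estimated correlation). The lipid receptor gene Trem2 stood at 11.4 ± 2.48 CPM in FFC and 0.981 ± 0.357 CPM in Chow (log2 3.53 ± 0.28, adjusted p = 1.21e-05), and the elastase gene Mmp12 at 42.8 ± 3.55 CPM in FFC and 0.821 ± 0.239 CPM in Chow (log2 5.70 ± 0.17, adjusted p = 1.96e-07). The member that fell was Fabp5, a fatty acid binding protein. In the monocyte list 10 of 10 tested members rose and 0 fell (median log2 2.20, camera adjusted p = 9.10e-05, and adjusted p = 0.265 with an estimated correlation). Of its members, 5 reached 1 CPM in Chow, and 1, Fn1, is in another list too. Ccr2, the receptor that draws monocytes into tissue, stood at 9.86 ± 1.02 CPM in FFC and 1.65 ± 0.270 CPM in Chow (log2 2.58 ± 0.16, adjusted p = 1.57e-06). In the pan-macrophage list 12 of 15 tested members rose and 0 fell (median log2 0.81, camera adjusted p = 1.46e-05, and adjusted p = 0.432 with an estimated correlation). In the resident Kupffer cell list 1 of 8 tested members rose and 1 fell (median log2 -0.68, camera adjusted p = 0.849), with medians of 0.26, -1.65 and -0.97 in FFC_1, FFC_2 and FFC_3. Its share of all counts went the other way, at 0.060 ± 0.017% in FFC and 0.034 ± 0.0017% in Chow (exact permutation p = 0.1). The member that rose was Cd5l, at log2 1.25 to 1.95 over the alternatives, and Fcna fell. A share is weighted to the abundant members, so it does not show a rise of the list at large. Timd4, a marker of long-lived resident macrophages, had 7.50, 0.663 and 1.40 CPM in the FFC libraries and did not pass (log2 -1.43 ± 0.94, adjusted p = 0.25, passing in 1 of 21 alternatives, namely without FFC_1 at log2 -3.03).

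Genes that recruit and hold leukocytes rose. Vcam1, an adhesion molecule of endothelium (ENSMUSG00000027962, chromosome 3, 116110020 to 116129688), stood at 42.0 ± 6.54 CPM in FFC and 11.2 ± 1.30 CPM in Chow (log2 1.91 ± 0.13, adjusted p = 2.63e-06). Icam1, another adhesion molecule, rose (log2 1.97 ± 0.13, adjusted p = 1.64e-06), as did Itgb2 (2.21 ± 0.13), the beta chain of leukocyte integrins. In the leukocyte adhesion list 13 of 17 tested members rose and 3 fell (median log2 1.55, camera adjusted p = 6.21e-05, and adjusted p = 0.427 with an estimated correlation). In the cytokines and chemokines list 13 of 22 tested members rose and 2 fell, or 14 and 2 adjusted over the list alone (median log2 1.28, camera adjusted p = 0.0116, and adjusted p = 0.427 with an estimated correlation). Ccl2, which attracts monocytes, stood at 6.47 ± 1.14 CPM in FFC and 0.864 ± 0.559 CPM in Chow (log2 2.88 ± 0.40, adjusted p = 0.000483, 3.56 without Chow_3), and Cxcl10 (1.82 ± 0.21), which attracts T cells, rose. The inflammatory cytokines Tnf (log2 1.11 ± 0.45, adjusted p = 0.0530, passing in 9 of 20 alternatives, among them without FFC_2 or Chow_1 at log2 1.34 and 1.45) and Il1b (log2 -0.06 ± 0.25, adjusted p = 0.861, passing in 0 of 21 alternatives) did not pass, and Il1b lay above 0 without FFC_3 or Chow_1 (log2 0.12 and 0.20), with the length trend removed (0.21) and with library size alone (0.43). In the pattern recognition and inflammasome list 16 of 21 tested members rose and 2 fell (median log2 1.26, camera adjusted p = 0.000290, and adjusted p = 0.427 with an estimated correlation), with a rise of the toll-like receptor genes Tlr1 (3.07 ± 0.24) and Tlr9 (3.51 ± 0.40). In the list of MHC class II antigen presentation 11 of 14 tested members rose and 0 fell (median log2 1.22, camera adjusted p = 0.000325, and adjusted p = 0.452 with an estimated correlation). In the list of interferon-stimulated genes 23 of 27 tested members rose and 1 fell (median log2 0.92, camera adjusted p = 1.93e-05, and adjusted p = 0.394 with an estimated correlation), among them the antiviral genes Ifit2 (1.89 ± 0.13) and Oasl2 (2.11 ± 0.18). The cytokine list was not called with library size alone or with the read total behind the RPKM values.

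Of 6 further cell type lists, camera called that of cholangiocytes as higher. In that list, markers of bile duct cells, 12 of 17 tested members rose and 0 fell (median log2 1.92, camera adjusted p = 0.0126, and adjusted p = 0.712 with an estimated correlation), with medians of 2.53, 1.61 and 1.30 in FFC_1, FFC_2 and FFC_3. Sox9, a transcription factor of duct cells and progenitors, rose (log2 1.64 ± 0.26, adjusted p = 0.00110), and the duct keratin Krt19 did not pass (log2 1.47 ± 0.68, adjusted p = 0.107, passing in 4 of 21 alternatives, 0.67 without FFC_1). The cholangiocyte list was not called with library size alone or with the read total behind the RPKM values. In the T and NK cell list 7 of 21 tested members rose and 1 fell (median log2 0.70, camera adjusted p = 0.279, called in 1 of 20 alternatives), where the cytokine receptor gene Il7r (1.40 ± 0.27) rose. Cd3e, a chain of the T cell receptor complex, had log2 0.81 (adjusted p = 0.0312), and did not pass without FFC_3, Chow_1, Chow_2 or Chow_3 (adjusted p = 0.126, 0.0528, 0.0643 and 0.0828). In the B and plasma cell list 2 of 12 tested members rose and 5 fell (median log2 -0.36, camera adjusted p = 0.635), whose median was 0.12 with library size alone and 0.27 with the read total behind the RPKM values, with a fall of Igj (-2.01 ± 0.32), the joining chain of secreted antibodies. In the dendritic cell list 5 of 12 tested members rose and 0 fell, or 4 and 0 adjusted over the list alone (median log2 0.77, camera adjusted p = 0.240), and Clec9a (1.75 ± 0.32), a receptor for dead cells, rose. In the neutrophil list 2 of 6 tested members rose and 1 fell, or 2 and 0 adjusted over the list alone (median log2 -0.05, camera adjusted p = 0.662). Its median was below 0 while its mean was 0.40, and its median was above 0 without FFC_3 (0.31), Chow_1 (0.53) or Chow_2 (0.049), with library size alone (0.44) and with the length trend removed (0.32). In the sinusoidal endothelial cell list 6 of 16 tested members rose and 5 fell, or 8 and 5 adjusted over the list alone (median log2 0.22, camera adjusted p = 0.753). Its median was -0.12 with the length trend removed. Vwf (2.13 ± 0.26, from 1.35 to 2.76 over the alternatives), a clotting factor of vessels, rose, and Clec4g (-1.21 ± 0.094), a lectin of sinusoids, fell.

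Secreted hepatocyte proteins fell in relative abundance. Alb, the serum albumin gene (ENSMUSG00000029368, chromosome 5, 90460889 to 90476603), stood at 37466 ± 3927 CPM in FFC and 87965 ± 9461 CPM in Chow (log2 -1.23 ± 0.17, adjusted p = 0.000152). In the hepatocyte secretory and identity list 1 of 20 tested members rose and 15 fell (median log2 -0.83, camera adjusted p = 0.000858, and adjusted p = 0.427 with an estimated correlation). The list held 10.6 ± 0.258% of all counts in FFC and 14.6 ± 0.717% in Chow (exact permutation p = 0.1). Its median was -0.36 with library size alone and -0.21 with the read total behind the RPKM values. The member that rose was Apob, the structural protein of very low density lipoprotein (ENSMUSG00000020609, chromosome 12, 7977648 to 8016835), at 6385 ± 183 CPM in FFC and 1991 ± 128 CPM in Chow (log2 1.68 ± 0.13, adjusted p = 3.46e-06). Over the alternatives the log2 fold change of Apob ran from 0.98 to 2.31. Among the members that did not pass were Trf, whose exons overlap those of Gm20425, and the hepatocyte transcription factors Foxa2 and Hnf4a (log2 -0.28 ± 0.12, adjusted p = 0.0680, passing in 5 of 21 alternatives). Hnf4a passed as lower in DESeq2, with the length trend removed without and with the replicate block, and without overlapping genes and pseudogenes (log2 -0.28, -0.50, -0.51 and -0.32). With the read total behind the RPKM values Hnf4a and Trf passed as higher (log2 0.34 and 0.43). In the periportal hepatocyte list 1 of 16 tested members rose and 10 fell (median log2 -1.20, camera adjusted p = 0.0179, and adjusted p = 0.622 with an estimated correlation), and its median was -0.73 with library size alone and -0.58 with the read total behind the RPKM values. The urea cycle genes Arg1 (log2 -1.85 ± 0.18, adjusted p = 1.67e-05) and Asl (-1.45 ± 0.16) fell. In the pericentral hepatocyte list 4 of 16 tested members rose and 8 fell (median log2 -0.35, camera adjusted p = 0.784), and its median was 0.12 with library size alone and 0.28 with the read total behind the RPKM values. In the acute phase response list 10 of 22 tested members rose and 7 fell (median log2 0.09, camera adjusted p = 0.0615, called in 9 of 20 alternatives, among them without FFC_3, Chow_1 or Chow_3 at medians of 0.12, 0.24 and 0.13), with a rise of Lcn2, an iron-sequestering protein, from 2.18 ± 0.905 CPM in Chow to 143 ± 33.1 CPM in FFC (adjusted p = 3.91e-05).

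Male-biased liver genes fell. In that list 0 of 16 tested members rose and 14 fell, or 0 and 16 adjusted over the list alone (median log2 -2.16, camera adjusted p = 6.20e-10, and adjusted p = 0.427 with an estimated correlation), with medians of -2.97, -1.91 and -2.16 in FFC_1, FFC_2 and FFC_3. Slco1a1, an organic anion transporter, fell (log2 -5.96 ± 0.74, adjusted p = 0.00154, -6.75 without FFC_2). Serpina1e, a protease inhibitor with close paralogs, stood at 43.2 ± 16.3 CPM in FFC and 8579.8 ± 2035 CPM in Chow (log2 -7.63 ± 0.42, adjusted p = 3.90e-06). The major urinary proteins, a family of pheromone carriers whose members share sequence, held further large falls, as in Mup7 (log2 -8.15 ± 0.93, adjusted p = 0.00101). The members that did not pass were Elovl3 and Cyp4a12b. With the length trend removed the list's median was -1.70, and it was -1.72 with library size alone and -1.56 with the read total behind the RPKM values. In the list of female-biased liver genes 6 of 12 tested members rose and 3 fell (median log2 0.77, camera adjusted p = 0.436), with a median of 0.14 without Chow_2. Among them, Cyp2b13, whose paralogs share sequence, had 548 counts in FFC and 2 in Chow, a ratio after scaling of 168 (95% exact interval 46.2 to 1388, counting error only).

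Proliferation and cell death genes rose. Mki67, a marker of cycling cells, stood at 10 ± 3.46 CPM in FFC and 0.661 ± 0.355 CPM in Chow (log2 3.90 ± 0.42, adjusted p = 0.000169), and Cdkn1a, a cell cycle inhibitor induced by p53, at 54.9 ± 11.7 CPM in FFC and 2.65 ± 1.19 CPM in Chow (log2 4.37 ± 0.39, adjusted p = 0.000245). In the cell cycle list 24 of 27 tested members rose and 2 fell (median log2 2.41, camera adjusted p = 2.98e-07, and adjusted p = 0.427 with an estimated correlation). The members that fell were Pcna and Tyms, both of DNA synthesis. In the cell death and p53 list 15 of 23 tested members rose and 1 fell (median log2 0.52, camera adjusted p = 0.00554, and adjusted p = 0.427 with an estimated correlation). Tnfrsf10b, a death receptor, rose (log2 3.22 ± 0.29, adjusted p = 9.28e-06). In the list of liver tumour and progenitor genes 9 of 17 tested members rose and 1 fell (median log2 1.58, camera adjusted p = 8.17e-05, and adjusted p = 0.427 with an estimated correlation). Of its members, 4 are in other lists too, and its medians were 1.94, 1.34 and 0.80 in FFC_1, FFC_2 and FFC_3. The annexin gene Anxa2 stood at 186 ± 18.9 CPM in FFC and 15.3 ± 1.23 CPM in Chow (log2 3.61 ± 0.11, adjusted p = 1.96e-07). Afp, a fetal liver protein (log2 -0.42 ± 0.19, adjusted p = 0.0765, passing in 0 of 21 alternatives, and log2 0.21 with the read total behind the RPKM values), and Gpc3, a glypican of liver tumours (log2 0.59 ± 0.39, adjusted p = 0.204, passing in 3 of 21 alternatives, among them without Chow_1 at log2 1.15), did not pass. In the unfolded protein and integrated stress response list, whose median was below 0 without FFC_3 (-0.045), Chow_2 (-0.0093) or Chow_3 (-0.0054) and with the length trend removed (-0.10), 7 of 23 tested members rose and 8 fell (median log2 0.03, camera adjusted p = 0.737), where Atf3 (2.23 ± 0.18) and Ddit3 (0.92 ± 0.15), both stress-induced transcription factors, rose. In the oxidative stress and NRF2 list 8 of 17 tested members rose and 6 fell, or 9 and 6 adjusted over the list alone (median log2 0.56, camera adjusted p = 0.303). The cystine transporter gene Slc7a11 (2.98 ± 0.38) rose and Sod1 (-1.30 ± 0.12), a superoxide dismutase, fell, while Nqo1, a quinone reductase, did not pass (log2 0.33 ± 0.14, adjusted p = 0.0659, passing in 8 of 21 alternatives, among them without FFC_1 or Chow_3 at log2 0.47 and 0.44).

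**Figure D2:**
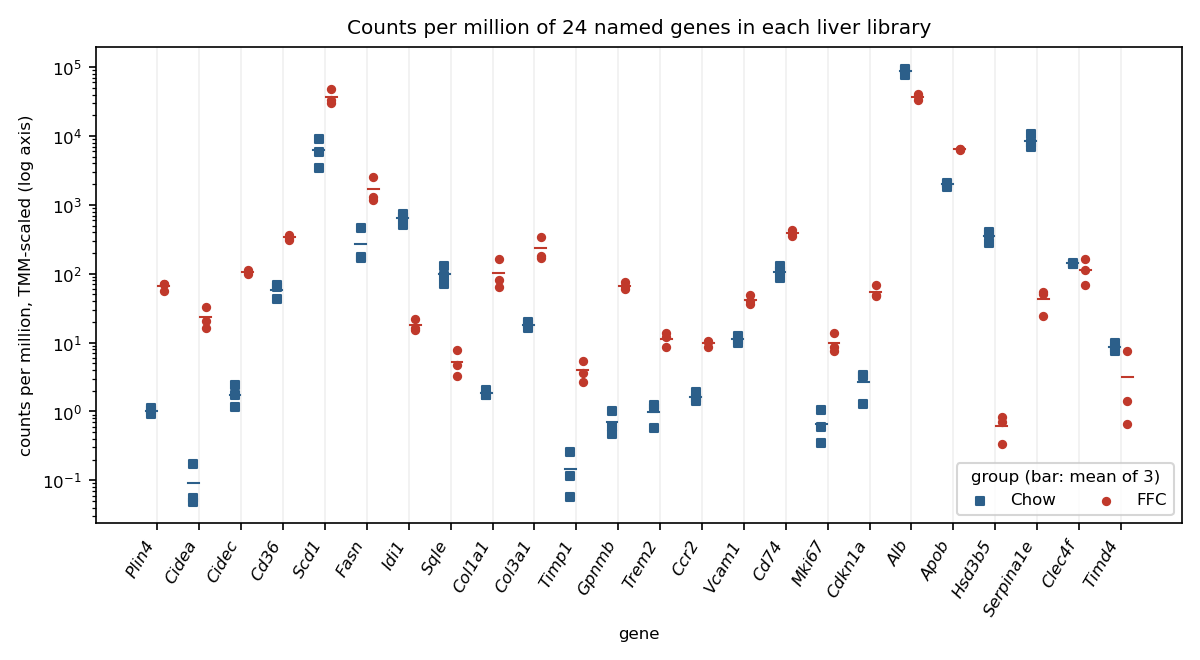
TMM-scaled CPM of 24 named genes in each of the 6 libraries, on a log axis, with bars at the group means (n = 3). Gpnmb stands at a mean of 67.2 CPM in FFC and 0.700 CPM in Chow, and Hsd3b5 at 0.624 and 355 CPM.

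Respiratory chain genes fell, and fold changes ran with gene length. In the oxidative phosphorylation list 1 of 23 tested members rose and 21 fell (median log2 -0.86, camera adjusted p = 1.68e-07, and adjusted p = 0.432 with an estimated correlation). Its median was -0.39 with library size alone and -0.24 with the read total behind the RPKM values. Ndufa4 and Ndufb8, both respiratory chain subunits, fell, with adjusted p = 4.04e-06 at log2 -1.63 and adjusted p = 1.83e-06 at log2 -1.58. The member that rose was Sdha, a subunit of succinate dehydrogenase. All 87 tested genes of cytosolic ribosomal proteins, a class chosen after its values were seen, fell (median log2 -1.57). Among 14000 protein-coding genes, the median log2 fold change went from -0.69 in the shortest of 10 classes by deposited gene length, with 174 genes higher and 830 lower, to 0.62 in the longest class, with 886 higher and 158 lower. With the trend on length removed, 8590 of the 10794 changed genes kept their call and direction and 86 passed with the opposite direction. The median of the oxidative phosphorylation list was then -0.61 (camera adjusted p = 1.51e-05), where over all alternatives with the preset correlation its adjusted p ran from 1.48e-12 to 7.09e-05.

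**Figure D3:**
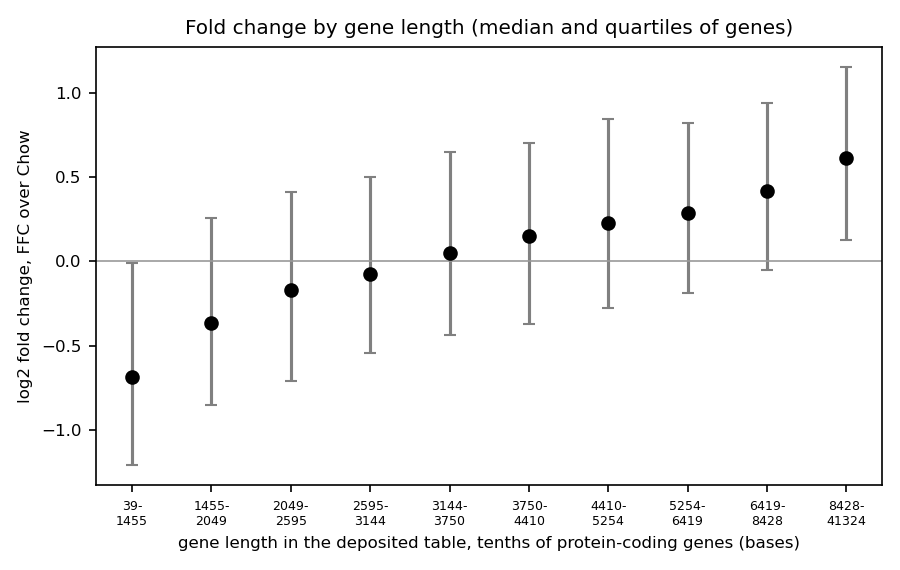
Log2 fold change of FFC over Chow for 14000 protein-coding genes in 10 classes of about equal size by deposited gene length in bases, with points at the median and bars at the quartiles of each class. The medians go from -0.69 in the shortest to 0.62 in the longest class.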

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

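The read total behind the RPKM values and leaving out overlapping genes and pseudogenes were alternatives chosen after seeing the data. Across all alternatives, 850 list results kept direction and side of the threshold, 36 newly passed, 28 no longer passed and 30, of 8 lists not called, changed direction without being called. Of the named gene results 4156 kept both, 53 newly passed, 58 no longer passed and 20 changed direction. Of 205 named genes 171 changed in every alternative. Many of them were named because they passed or had a small p in the main fit, so this does not speak for genes at large. Counts of changed genes stayed within 1.5 times in 80 cases and moved in 4: with library size alone 8891 genes were higher and 2755 lower, and with the RPKM read total 10033 and 2098. Of the shares of counts 37 stayed within 1 SD and 8 moved, among them the log2 ratio of hepatocyte secretory and identity (-0.20 with the 20 most abundant and the mitochondrial genes out of the total). The cause was not tested, and this holds for each change given here. Medians are in brackets. With an estimated correlation, which leaves medians as they are, 0 of 45 lists were called, so these no longer passed: cholesterol synthesis and uptake (-1.86), fatty acid oxidation and ketogenesis (0.41), lipid droplet proteins (0.77), collagens and matrix (2.60), matrix remodelling and TGF-beta (1.78), hepatic stellate cell (0.44), pan-macrophage (0.81), monocyte (2.20), lipid-associated macrophage (2.51), cholangiocyte (1.92), hepatocyte secretory and identity (-0.83), periportal hepatocyte (-1.20), cytokines and chemokines (1.28), leukocyte adhesion (1.55), pattern recognition and inflammasome (1.26), MHC class II antigen presentation (1.22), interferon-stimulated genes (0.92), cell death and p53 (0.52), cell cycle (2.41), liver tumour and progenitor genes (1.58), male-biased liver genes (-2.16), oxidative phosphorylation (-0.86) and erythroid cell (-1.07). Of the 23 called lists, 20 were called under all alternatives but that one (highest adjusted p 0.0374). Of the 22 lists not called, 15 were called under none. No longer passing were cholangiocyte (2.42) and cytokines and chemokines (1.75) with library size alone, cholangiocyte (2.57) and cytokines and chemokines (1.91) with the RPKM read total, and erythroid cell (-0.73) with the length trend removed. Newly passing were fatty acid synthesis (1.09), acute phase response (0.13), cytochrome P450 and conjugation (-0.61) and immediate early genes (0.83) without a filter, fatty acid synthesis (1.05), sterol efflux and esterification (0.50), acute phase response (0.0897), cytochrome P450 and conjugation (-0.65) and immediate early genes (0.80) in DESeq2, fatty acid synthesis (1.06) and cytochrome P450 and conjugation (-0.65) in limma-voom, acute phase response (0.15) without the 20 most abundant genes, acute phase response (0.34) and immediate early genes (0.86) with the length trend removed, and sterol efflux and esterification (1.14) and exocrine pancreas (-1.22) with the RPKM read total. Leaving out each library in turn gave medians from 0.86 to 1.12 for fatty acid synthesis, 0.43 to 0.54 for sterol efflux and esterification, 0.00145 to 0.24 for acute phase response, -0.73 to -0.54 for cytochrome P450 and conjugation, 0.71 to 0.94 for immediate early genes, and -1.99 to -1.70 for exocrine pancreas, each with some libraries left out newly passing. The opposite direction, without a call, was found for B and plasma cell (0.12), neutrophil (0.44), pericentral hepatocyte (0.12) and circadian clock (0.32) with library size alone, B and plasma cell (0.27), neutrophil (0.59), pericentral hepatocyte (0.28) and circadian clock (0.48) with the RPKM read total, neutrophil (0.32), sinusoidal endothelial cell (-0.12), unfolded protein and integrated stress response (-0.10) and adipose tissue (-0.13) with the length trend removed, neutrophil (0.31) and skeletal muscle (2.39) without a filter, neutrophil (0.30) and skeletal muscle (1.03) in DESeq2, neutrophil (0.00288) with upper-quartile scaling, and unfolded protein and integrated stress response (-0.00413) without overlapping genes and pseudogenes. Leaving out each library gave ranges across 0 for neutrophil (-0.21 to 0.53), unfolded protein and integrated stress response (-0.0452 to 0.16), adipose tissue (-0.0740 to 0.15) and skeletal muscle (-0.81 to 0.00186), and for Il1b (-0.25 to 0.20). Leaving out libraries gave 9866 changed genes without FFC_1 and 10368 without Chow_3. Genes that passed with the opposite sign were Apoe (0.34 with library size alone, 0.50 with the RPKM read total) and, with the RPKM read total, Gm20425 (0.43), Hnf4a (0.34) and Trf (0.43). Genes with the opposite sign that did not pass were Afp (0.0559), Clec4f (0.19), Gm20425 (0.27), Hnf4a (0.18), Il1b (0.43) and Trf (0.27) with library size alone, Afp (0.21), Clec4f (0.35) and Il1b (0.59) with the RPKM read total, and Apoe (0.11) and Il1b (0.21) with the length trend removed. Thinning to the smallest library gave 10670 changed genes, and 10567 of the 10794 kept call and direction.

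The labels do not say whether a replicate number pairs samples. Residuals of libraries with the same number correlated across genes at -0.0477, 0.0262 and -0.0628, and genes are not independent replicates. These values show no shared signal but cannot tell whether the animals were paired. With the number as a block, 10227 genes changed. Newly passing were fatty acid synthesis (1.06), acute phase response (0.13), cytochrome P450 and conjugation (-0.66) and exocrine pancreas (-1.84) with the block, and fatty acid synthesis (0.83), T and NK cell (1.05), acute phase response (0.34), immediate early genes (0.86) and exocrine pancreas (-1.44) with the block and the length trend removed. The latter gave the opposite direction, without a call or a pass, for neutrophil (0.31), sinusoidal endothelial cell (-0.11), unfolded protein and integrated stress response (-0.0993) and adipose tissue (-0.11) and for Apoe (0.11) and Il1b (0.22).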

Other observations

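Immediate early genes, which respond within minutes to stimuli, went both ways. In that list 10 of 17 tested members rose and 5 fell (median log2 0.80, camera adjusted p = 0.0848, called in 5 of 20 alternatives, among them without FFC_3 at a median of 0.94). Egr2, a zinc finger transcription factor, rose (log2 3.81 ± 0.32, adjusted p = 6.29e-06). In the circadian clock list 2 of 19 tested members rose and 6 fell, or 1 and 6 adjusted over the list alone (median log2 -0.15, camera adjusted p = 0.655), whose median was 0.32 with library size alone and 0.48 with the read total behind the RPKM values, with a rise of Npas2 (3.92 ± 0.57, 4.70 without Chow_3), a clock activator, and a fall of Nr1d2 (-1.32 ± 0.23), a clock repressor. Times of tissue collection are not in the labels. In the erythroid cell list 0 of 6 tested members rose and 6 fell (median log2 -1.07, camera adjusted p = 0.00539, and adjusted p = 0.427 with an estimated correlation), with a fall of Alas2 (-1.59 ± 0.16), the first enzyme of heme synthesis in red cell precursors. The erythroid median was -0.60 with library size alone and -0.45 with the read total behind the RPKM values. With the length trend removed it was -0.73 (camera adjusted p = 0.0595, from 0.00113 to 0.0595 over the alternatives with the preset correlation).

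Markers of neighbouring tissues gave no call in the main camera test. In fry, exocrine pancreas (adjusted p = 0.00297), adipose tissue (0.0401) and mesothelium and liver capsule (0.0401) passed, and skeletal muscle (0.0620) did not. In the adipose tissue list 2 of 5 tested members rose and 1 fell (median log2 0.07, camera adjusted p = 0.436), with a median of -0.074 without Chow_3 and -0.13 with the length trend removed. Its risers were Cfd, a complement protease, and Cidea, which is also in the lipid droplet list, and Car3, a carbonic anhydrase, fell. In the exocrine pancreas list 0 of 2 tested members rose and 2 fell (median log2 -1.85, camera adjusted p = 0.111, called in 4 of 20 alternatives, among them without Chow_3 at a median of -1.99). In the skeletal muscle list 0 of 1 tested members rose and 0 fell, or 0 and 1 adjusted over the list alone (median log2 -0.90, camera adjusted p = 0.715), with values of -0.18 without FFC_3, -0.0070 without Chow_1 and 0.0019 without Chow_3, and above 0 without a filter (2.39) and in DESeq2 (1.03). In the mesothelium and liver capsule list 3 of 8 tested members rose and 0 fell (median log2 0.60, camera adjusted p = 0.209), where the risers were Wt1, a transcription factor of mesothelium (log2 2.07 ± 0.54, adjusted p = 0.00745, 2.86 without Chow_1), and Krt8 and Krt18, which are also hepatocyte keratins. Processed pseudogenes, a class chosen after its values were seen, had 24 members higher, 374 lower and 336 not changed in edgeR.

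Of the tests given here, those on GC content and on the splits of the libraries were chosen before their results were seen. Refits with the length trend removed and with other scalings were planned before the data were examined, except for the RPKM read total, but setting them against these patterns, like the remaining tests, was chosen after the patterns were seen. The 6 libraries can be split into 3 and 3 in 10 ways, too few for a share under 0.05. Among them 1 split, the real one, gave 10794 changed genes in edgeR. The highest of the other splits gave 0, with at most 140 genes at an unadjusted p under 0.05. Each of the other splits holds FFC and Chow libraries in both of its groups. The difference between the diets then adds to the spread within groups, which keeps these counts low. The contrast of 10794 with 0 therefore does not measure chance. Other tools were not run on the splits.

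Short genes were lower and long genes higher in FFC, and the median log2 fold change of the shortest of 10 length classes minus that of the longest was -1.30. Without the ribosomal protein and respiratory chain genes the difference was -1.22. These made up 117 of the 1401 genes in the shortest class, too few to move its median by much. The trend was thus not confined to them, and leaving them out tests no more than that. Within 3 classes by GC content the difference was -1.23 or more negative, which argues against GC content as the whole cause. With the length trend removed the respiratory chain list kept a median of -0.61, from -0.86. It stayed called by camera with the preset correlation (adjusted p = 0.432 with an estimated correlation before removal). This argues against the length trend as fitted (lowess, span 0.4) as the whole cause of the fall. Such a wide smooth may correct too little among the shortest genes, which was not tested. Scaling could account for most of the size of the fall, since the median was -0.24 with the RPKM read total. It cannot be told apart from a change in these genes. For the shortest minus the longest class, the 3 FFC libraries averaged -1.31 ± 0.148 and the 3 Chow libraries -0.00340 ± 0.0680. These values are relative to the Chow mean, so the Chow average is near 0 by construction. A length-dependent difference in RNA quality or library preparation may underlie the trend. It cannot be told apart from an effect of the diet on short genes. Every FFC library differs from every Chow library, and the labels give no RNA quality.

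Male-biased liver genes fell, with a median log2 fold change of -2.16. The FFC libraries were not from female mice as far as the 4 Y genes Ddx3y, Eif2s3y, Kdm5d and Uty show, which summed to at least 98.0 CPM in each, against 158 ± 7.42 CPM in Chow. A lower share of hepatocyte RNA would move them like secreted hepatocyte proteins. But the difference of their median from that list's was -1.14 or more negative in each FFC library. Of the 16 tested members, 15 lie outside the Mup family, where paralogs share reads, and these had a median of -2.31. Since so little of the list was left out, this median does not test for shared reads. A change of sex-dependent expression in hepatocytes with the diet may underlie the fall and stays open as a hypothesis, and no hormone was measured.

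Monocyte, lipid-associated macrophage and collagen genes rose and secreted hepatocyte genes fell. A lower share of hepatocyte RNA would raise markers of all other cell types alike. But the monocyte median lay at least 1.01 above those of sinusoidal endothelial, T and NK, and B and plasma cells in each FFC library. Of the tested members, 3 of 21 for T and NK cells and 7 of 12 for B and plasma cells reached 1 CPM in Chow. For monocytes these were 5 of 10 and for endothelial cells 16 of 16. The T and NK median thus rests mostly on genes under 1 CPM in Chow. Cholangiocytes, with medians of 2.53, 1.61 and 1.30 in FFC_1, FFC_2 and FFC_3, rose as well, however. They lay above monocytes in FFC_1 and within 1 of them in the others. The comparison was made for monocytes alone. In FFC_3 the lipid-associated macrophage and collagen medians were 1.81 and 2.33, against 0.92 for T and NK cells. Under the scalings tried, the lowest median of the 3 lists was 2.19. These scalings shifted the log2 fold changes by a median of -0.010 to 0.63. None could have lowered the rise by much, so they do not test whether scaling contributed to it. For the fall of secreted hepatocyte genes, scaling could account for most of its size, since the median was -0.21 with the RPKM read total, and cannot be told apart from a change in these genes, as the data hold no outside standard. More monocytes, macrophages and matrix-producing cells, or more expression per cell, may each underlie the rise, and whole-tissue RNA does not separate them.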
